A study of Mus musculus with 2 samples.

How the data were processed

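The assay was ChIP-seq of H3K9ac in intestine dissected from mouse embryos of day 16.5, in 2 biological replicates of 1 group, each a pool of both sexes. The analysis started from 4 deposited peak lists on the mm10 assembly, 1 for each replicate, a combined list and a list of replicated peaks. The deposited enrichment values are ratios made by the authors, the signal value of each peak in the narrowPeak format. The peak caller behind them, its version, its thresholds and the read filters are not given in the sources used here. Further columns of the deposited lists hold the authors' −log10 p and −log10 q of each peak and the position of its summit. Per the deposited file descriptions, the replicate 1 list was derived from its alignment and 2 further inputs, the replicate 2 list from its alignment and 1 further input shared with replicate 1, and the combined list from both alignments and 2 further inputs. The roles of these inputs are not named. The replicated list was made from the combined and per-replicate lists, and its 42782 peaks on assembled chromosomes were all found in the combined list. No reads, read counts or signal tracks were among the files, and no control sample, so the depth per sample is unknown and no interval for counting error can be given for an enrichment. Intervals in the text are 95% Wilson intervals for shares of genes.

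Peaks on the assembled chromosomes were compared with the GRCm38 genome sequence, the same assembly, and with GENCODE annotation release M21, which lists 21853 protein-coding genes with 54361 transcription starts. Peaks on scaffolds outside these chromosomes were left out of the comparisons. Peaks of the replicates counted as shared when the overlap was at least 50% of the length of either. Random placement put peaks of the same lengths on the same chromosomes, outside 244 assembly gaps of at least 1 kb, 100 times. A promoter was the 1 kb to either side of any annotated start of a protein-coding transcript. A gene's enrichment in a replicate was that of the strongest peak overlapping its promoter in that replicate's list. Means and SDs of these values are over the 2 replicates, for genes with a replicated promoter peak. Location classes were taken in the order promoter, other exon, intron and intergenic. Distal peaks lay more than 2.5 kb from every protein-coding start and were assigned to the gene of the nearest start, and a gene's territory ran to the midpoints with its neighbours. Domains were replicated peaks merged over gaps of up to 1 kb, and the widest 5% of those at promoters were called broad.

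There were 28 gene lists, of which 26 were written from general knowledge of the tissue and held 667 genes, 2 of them in more than one list. The olfactory and vomeronasal receptor lists were taken from gene symbols. Of the written names 4 (Pla2g2a, Ahsp, Amy2b and Claudin18) matched no protein-coding gene. The gene lists, the 20 sequence strings, the comparisons with their tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule named up to 4 genes of each list with the highest mean enrichment at a replicated promoter peak and up to 4 without such a peak in alphabetical order, the 10 genes with the highest enrichment, the 10 with the widest promoter domain, the 10 list genes with most distal peaks, and every Hox gene.

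List shares with a promoter peak or a broad domain were compared with other genes by Fisher's exact test, two-sided. List medians of log2 enrichment were compared with 100000 random lists of marked genes, two-sided, for lists with at least 5 such genes. Mean numbers of distal peaks were compared with 10000 random lists matched on decile of territory length, one-sided for more. Strings were counted on both strands in the 500 bp around each distal summit and in windows of equal length 5 kb downstream without a peak, compared by Fisher's exact test, two-sided, and set beside up to 20 shuffled strings of the same bases, of which KLF allows 7. Shuffled strings absent from the windows gave no ratio and were left out. Adjusted p-values are Benjamini-Hochberg values over the lists or strings of each comparison, with a threshold of 0.05. Genes and peaks are not independent replicates, so these tests describe the lists in these 2 pools. With 1 group of 2 samples, no test between samples was made.

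Alternatives were an enrichment of at least 4, a −log10 q of at least 2, other overlap rules, equal numbers of peaks, the combined list, each replicate left out in turn, promoter windows of 500 bp and 2.5 kb, the 5′ end of the gene alone, random lists matched on decile of promoter CpG content, distal limits of 10 kb and 100 kb, merging over 3 kb or none, the widest 10%, windows of 200 bp, windows upstream, and windows matched on GC content in classes of 2%. Added after the data were seen were replicated peaks with a partner in both per-replicate lists, and peaks in the promoter window of no other gene.

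The steps for replicate overlap, promoter shares, enrichment, distal peaks and the finding of strings were tested on simulated data. The location, CpG-matched, broad domain and string frequency comparisons were not simulated. Simulated values did not depend on promoter CpG content, whereas enrichment in the data did (Spearman's rho 0.506). The shares of simulated lists called therefore need not hold for the data. Of 75014 placed peaks 50.0% were copied and 51.3% were found shared. For promoter shares 98.4% of planted lists of sufficient size and 2% of unchanged lists were called, for enrichment 97.8% and 0%, and for distal peaks 98.9% and 0.909%. Effects planted in lists were of a set size, and smaller ones were not tried. In each of these steps planted lists with few genes, such as the middle Hox genes, were not scored. Simulated distal counts were independent draws in proportion to territory length, whereas counts in the data ran up to 107 at Gse1. Planted copies of all 20 strings were found in 5000 simulated windows. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and a random seed of 1.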

Results

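Acetylation of histone H3 at lysine 9 (H3K9ac), a mark found at active promoters and many active enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in intestine from mouse embryos of day 16.5. The samples were 2 biological replicates of 1 group, each a pool of male and female embryos of the strain B6NCrl, and the pool of replicate 2 held 41 embryos per its labels. The labels give both pools the same donor identifier, so how far they are independent is unknown. With no other tissue, stage or treatment in the group, the comparisons were those between the replicates, between the marked sites and the genome, and between gene groups. No control sample was among those analysed here. The peak lists carry no read counts, so the sequencing depth behind each value is unknown. The replicate 1 list held 75020 peaks covering 41.1 Mb, or 1.51% of the mm10 assembly. The replicate 2 list held 63147 peaks covering 33.9 Mb, or 1.24%. The authors' combined list of both replicates held 91601 peaks and their list of replicated peaks 42788, with median widths of 300 bp and 637 bp. Each peak's enrichment below is the authors' own value, a ratio whose median was 3.76 in replicate 1 and 3.97 in replicate 2.

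The strongly marked sites of the embryonic intestine were found in both pools, and the weak ones mostly in one of them. Of 75014 replicate 1 peaks on the assembled chromosomes, 36885 (49.2%) shared at least 50% of the length of either peak with a replicate 2 peak. In the other direction 40277 of 63138 peaks (63.8%) were shared. Random placement of peaks of the same lengths on the same chromosomes gave 2.04% and 2.58% on average, and no more than 2.25% and 2.86% in any of 100 placements. The permutation p was 0.0099, the smallest that 100 placements can give. Sharing rose with enrichment. It was 15.5% for replicate 1 peaks with an enrichment under 3, 64.6% from 4 to 6, 97.2% from 6 to 10, and 100% for all 5696 peaks at 20 or more. Peaks within 1 kb of a protein-coding transcription start were shared in 81.3% of replicate 1 cases and 89.0% of replicate 2 cases. Beyond 2.5 kb from every such start the shares were 32.2% and 45.7%. Across the 36885 shared peaks, enrichment in the replicates had a Spearman's rho of 0.841 and, on the log2 scale, a Pearson's r of 0.888, and 82.4% of pairs lay within 1.5-fold. The SD between replicates was 0.36 on the log2 scale. Peaks and genes are not independent replicates, so these values describe the 2 pools.

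**Figure D1:**
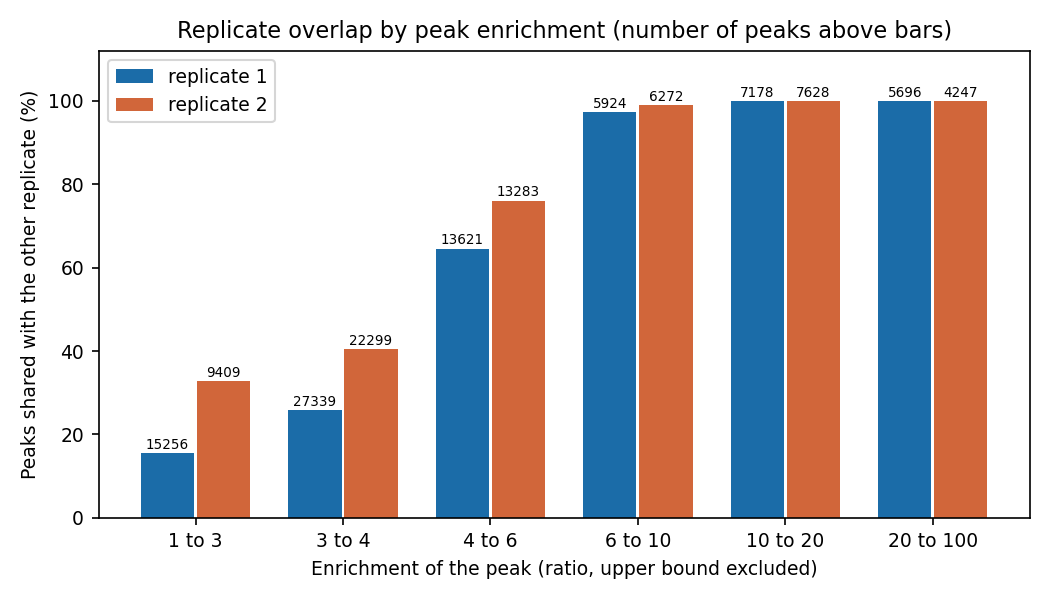
Percentage of peaks of each replicate (y axis) that shared at least 50% of either peak's length with a peak of the other replicate, by the enrichment ratio of the peak (x axis), with the number of peaks above each bar. The share ran from 15.5% of replicate 1 peaks under 3 to 100% at 20 or more.

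Peaks that the authors kept as replicated were stronger, wider and nearer to gene starts than the other peaks of the combined list. Their median enrichment was 5.16 over 42782 peaks against 2.84 over the other 48809, a ratio of 1.82. Median widths were 637 bp and 217 bp, and 46.3% against 10.2% lay within 1 kb of a protein-coding start. The authors made the replicated list from the combined and per-replicate lists by a rule not given in the sources used here, and no test was made of this difference. All 35661 combined peaks with a partner in both per-replicate lists were in it. A further 7121 of its peaks (16.6%) had no such partner in at least one list.

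Promoters carried the mark far more often than chance. Of the 42782 replicated peaks on assembled chromosomes, 19814 (46.3%) lay within 1 kb of a protein-coding start, against 3.81% of randomly placed peaks, 12.2 times as many. Introns held 25.2% (32.4% at random), other exons 7.51% (7.10% at random), and intergenic sequence 20.9% (56.7% at random). Each of these 4 shares lay outside the range of 100 random placements, with a two-sided permutation p of 0.0198, the smallest they can give. The slight excess in exons turned into a deficit among peaks with an enrichment of at least 4, where the share was 5.82% against 7.90% at random, among peaks with partners in both per-replicate lists (6.89% against 7.475%) and with promoter windows of 2.5 kb (5.48% against 6.39%). It was larger in the combined list (9.31% against 5.56%), without replicate 1 (7.71% against 5.54%) and without replicate 2 (8.46% against 5.58%). The excess was also larger with the 5′ end of the gene alone (13.2% against 7.84%) and with promoter windows of 500 bp (8.36% against 7.38%). The deficit in introns turned into an excess in the combined list, 37.4% against 34.2% at random (permutation p = 0.0198), and was not detected without replicate 2, 34.2% against 34.2% (permutation p = 0.713). Promoter peaks were also stronger, with a median enrichment of 13.5 against 4.09 in exons, 3.80 in introns and 4.19 between genes.

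Replicated promoter peaks lay at 14361 of 21853 protein-coding genes (65.7%). The 10 highest entries, as means ± SD over the 2 replicates here and below, were led by Srsf6 at 47.2 ± 2.502, a splicing factor gene (chromosome 2, 162931528 to 162937121). Irf2bp2, a transcriptional cofactor, had 45.6 ± 0.319 and Rps19, a ribosomal protein gene, 45.4 ± 0.405. Eif4g2 (translation initiation) had 44.7 ± 3.58 and Kmt5b (a histone H4 methyltransferase) 44.3 ± 1.44. H3f3a (histone H3.3) had 43.6 ± 1.98 and Ddx6 (an RNA helicase) 43.6 ± 2.92. H1f0, a linker histone gene, and Gcat shared a peak at 44.4 ± 0.958, and Gcat filled 2 of the 10 places because the annotation lists it under 2 gene identifiers. Over the 14148 genes with a value in both replicates the median was 17.2, Spearman's rho was 0.914 and the SD between replicates 0.26 on the log2 scale. Promoters were marked in both per-replicate lists for 14212 genes, in replicate 1 alone for 617 and in replicate 2 alone for 274.

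The lists of intestinal epithelial transcription factors, general epithelial, stem cell and Wnt target, proliferation and housekeeping genes were marked almost without exception. All 31 genes in the list of intestinal epithelial transcription factors, which also holds the hedgehog ligands Ihh and Shh, had a replicated promoter peak (95% Wilson interval 89.0 to 100%). The highest were Tcf7l2, the main Wnt effector of the gut, at 30.1 ± 1.52 (chromosome 19, 55741820 to 55933654), Klf5 at 25.98 ± 1.84, Ihh at 24.5 ± 1.24 and Gata6 at 23.3 ± 1.79. All 24 general epithelial genes were marked too, led by the E-cadherin gene Cdh1 at 22.2 ± 2.08 (chromosome 8, 106603351 to 106670246), the protease inhibitor gene Spint2 at 22.1 ± 2.96, Prom1 at 19.7 ± 1.64 and the membrane protease gene St14 at 18.9 ± 3.36. Of 26 stem cell and Wnt target genes, 25 had a peak, among them the R-spondin receptor gene Lgr4 at 30.0 ± 0.198, Lrig1 at 28.6 ± 2.67, the Notch target Hes1 at 24.3 ± 3.59 and the Wnt target Axin2 at 23.2 ± 2.91. Olfm4 had none in the replicated list, the list meant below wherever a gene is said to have no peak. Some of these genes had a peak in another list. All 30 proliferation genes were marked, with Mki67 at 25.3 ± 0.865, Cdk4 at 23.8 ± 1.19 and Cdk1 at 23.7 ± 2.18. The highest of them, Aurka at 31.3 ± 4.77, had no peak outside the promoter window of its neighbour Cstf1. All 32 housekeeping genes had one, led by Ywhaz at 41.9 ± 2.46, Eef1a1 at 37.0 ± 2.69, Ubc at 35.3 ± 1.36, a peak of which also lay in the window of Gm10382, and Rpl13a at 32.0 ± 2.18. Against about 65.7% of all other protein-coding genes, Fisher's exact test (two-sided, Benjamini-Hochberg over 28 lists) gave p-values of 3.31e-06, 5.05e-05, 0.000555, 5.88e-06 and 1.93e-06 in the order given, and adjusted exact p-values of 1.16e-05, 0.000109, 0.000972, 1.83e-05 and 9.00e-06. Against random genes matched on the CpG content of their promoters, the calls for stem cell, proliferation and housekeeping genes ended, with adjusted permutation p-values of 0.461, 0.438 and 0.684. Over the 10 alternatives tried, their adjusted exact or permutation p ran from 1.64e-05 to 0.461, from 3.13e-06 to 0.438 and from 1.33e-06 to 0.684.

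Lists of connective tissue, smooth muscle and pacemaker cell genes were also marked in all or nearly all cases. All 36 intestinal mesenchyme and fibroblast genes had a promoter peak (Wilson interval 90.4 to 100%, exact p = 3.84e-07, adjusted p = 2.15e-06, Fisher's exact test). The hedgehog receptor gene Ptch1 had 25.1 ± 2.07, Zeb2 22.0 ± 2.16, Foxf1, a hedgehog target needed for gut mesenchyme, 21.3 ± 0.454 (chromosome 8, 121084386 to 121088144), and Tcf21 20.4 ± 1.58. Of 30 smooth muscle genes, 29 were marked (96.7%, interval 83.3 to 99.4%, exact p = 7.04e-05, adjusted p = 0.000141). Srf, the master regulator of smooth muscle genes, had 35.7 ± 0.376 (chromosome 17, 46548329 to 46556175), Vcl 28.0 ± 2.05, Tpm1 25.6 ± 2.62 and the Srf cofactor gene Mrtfa 25.2 ± 1.89, and Kcnmb1 had no peak. All 10 genes of interstitial cells of Cajal, the pacemaker cells of the gut, were marked, led by Pde3a at 24.1 ± 3.20, Edn3 at 13.1 ± 1.11, Gucy1a1 at 13.005 ± 1.34 and Hand1 at 11.4 ± 1.01 (exact p = 0.0192, adjusted p = 0.0255). With replicate 1 alone, that is without replicate 2, this last adjusted exact p was 0.0569, and with CpG-matched genes the adjusted permutation p was 0.612. Its adjusted exact or permutation p ran from 0.00418 to 0.612 over the 10 alternatives.

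Enterocyte genes were marked in 32 of 40 cases, a share (80.0%, Wilson interval 65.2 to 89.5%) that did not pass the test against all other genes (exact p = 0.066, adjusted p = 0.0804, Fisher's exact test). Maf had 25.8 ± 0.107, the triglyceride synthesis gene Dgat1 20.3 ± 2.69, Mttp, which loads lipid onto lipoproteins, 18.3 ± 1.42, and the peptidase gene Dpp4 14.6 ± 0.00276. A promoter peak of Mttp also lay in the window of Trmt10a. Abcg5, Ace2, Mep1b and Myo1a were among the 8 without a replicated peak. Random genes of matched promoter CpG content were marked in 40.3% of cases, and the list lay above them (adjusted permutation p = 0.000622). The adjusted exact p was 0.0345 with replicate 2 alone and 0.0849 with replicate 1 alone. It also passed with the combined list, with windows of 2.5 kb and with peaks in the window of no other gene. Over all 10 alternatives the adjusted exact or permutation p ran from 0.000622 to 0.449.

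Enteroendocrine, and Paneth and tuft cell genes were marked less often than other genes, and goblet cell genes did not pass the test. Goblet cell and secretory progenitor genes had a peak in 12 of 21 cases (57.1%, exact p = 0.491, adjusted p = 0.528, Fisher's exact test). The secretory regulator Xbp1 had 36.0 ± 3.86 (chromosome 11, 5520659 to 5525893), St6gal1 18.5 ± 1.62, the Notch ligand gene Dll1 17.3 ± 0.956 and Creb3l1 14.9 ± 1.36, whereas Agr2, Bcas1, Clca1 and Ern2 had none. Of 28 enteroendocrine genes 10 were marked (35.7%, exact p = 0.00206, adjusted p = 0.00339), with Cpe at 14.3 ± 0.187, the secretin gene Sct at 10.5 ± 0.703, Gck at 7.98 ± 1.37 and Isl1 at 7.18 ± 3.58. The other 18 included Arx, Chga, Chgb and Fev. Paneth and tuft cell genes had a peak in 7 of 19 cases (36.8%, exact p = 0.0132, adjusted p = 0.0185). These were led by the tuft cell genes Plcg2 at 11.5 ± 0.846 and Pou2f3 at 8.37 ± 2.22, with Dclk1 at 7.02 ± 0.597 and Hck at 6.94 ± 0.964, while Alox5ap, Ang4, Avil and Chat had no replicated peak, although Avil had one in both per-replicate lists and Chat in replicate 1. Without replicate 2, in the longer list of replicate 1, both lower calls ended, with 57.1% and 52.6% marked (adjusted exact p = 0.257 and 0.255). Against CpG-matched genes the enteroendocrine call held (adjusted permutation p = 0.000622) and the Paneth and tuft call ended (adjusted permutation p = 1). For these 2 lists the adjusted exact or permutation p of the 10 alternatives ran from 0.000622 to 0.257 and from 0.00199 to 1.

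The lists of the enteric nervous system, the vessels and the mesothelium did not pass the test in either direction. Enteric nervous system genes were marked in 23 of 34 cases (67.6%, adjusted exact p = 1, Fisher's exact test). Tbx3 had 22.2 ± 4.93, the neuregulin receptor gene Erbb3 17.0 ± 3.84, Hand2 15.6 ± 0.789 and Elavl4 11.9 ± 0.357, and Dbh, Fabp7, Nos1 and Phox2b were among those without a peak. Endothelial and lymphatic genes were marked in 23 of 28 cases (82.1%, exact p = 0.0741, adjusted p = 0.0864). Egfl7 had 16.3 ± 4.38, Lmo2 14.2 ± 1.0302, Fli1 13.6 ± 0.476 and the lymphatic regulator Prox1 11.7 ± 3.67. Emcn, Flt4, Lyve1 and Mmrn1 had no replicated peak. Mesothelial genes were marked in 9 of 14 cases (64.3%, adjusted exact p = 1), led by Podxl at 17.5 ± 0.3003, Aldh1a2 at 7.24 ± 2.22, Tbx18 at 6.62 ± 0.256 and Rspo1 at 5.58 ± 0.809, and Gpm6a, Krt14, Msln and Muc16 were without. With replicate 2 alone the endothelial list passed, at 89.3% and an adjusted exact p of 0.0125, and it also passed with the combined list and with peaks in the window of no other gene. The range over its 10 alternatives was an adjusted exact or permutation p of 0.00512 to 0.751.

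Blood cell genes were marked less often than other genes. Only 8 of 30 leukocyte genes had a peak (26.7%, Wilson interval 14.2 to 44.4%, exact p = 1.78e-05, adjusted p = 4.97e-05, Fisher's exact test). They were led by the myeloid regulator Irf8 at 10.8 ± 0.433, Ikzf1 at 7.28 ± 0.690, Rorc at 5.99 ± 1.80 and Coro1a at 5.81 ± 0.889, and the macrophage genes Adgre1, C1qa, C1qb and C1qc had no replicated peak, although C1qa and C1qb had one in replicate 1. Erythroid genes were marked in 8 of 21 cases (38.1%, exact p = 0.0106, adjusted p = 0.0165). Klf1, the master regulator of red cell genes, had 23.8 ± 5.59, the transferrin receptor gene Tfrc 22.7 ± 3.15, the haem synthesis gene Hmbs 19.5 ± 1.84 and Sptb 9.89 ± 1.17. Alas2, Epb42, Gata1 and the alpha-globin gene Hba-a1 had no replicated peak. With CpG-matched genes neither call held (adjusted permutation p = 0.438 for leukocyte genes and 0.510 for erythroid genes), and the erythroid share of 38.1% then lay above the 30.0% of matched genes. Adjusted exact or permutation p-values of the 10 alternatives ran from 1.60e-08 to 0.438 for leukocyte genes and from 0.00852 to 0.510 for erythroid genes.

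Marker genes of other organs were marked rarely. Liver genes had a promoter peak in 7 of 30 cases (23.3%, exact p = 2.52e-06, adjusted p = 1.01e-05, Fisher's exact test), and the most abundant liver products, Afp, Ahsg and Alb, had none in any list, nor did Ambp in the replicated list. The highest 2, Apoh at 21.0 ± 1.26 and Trf at 8.13 ± 2.90, had no peak outside the promoter windows of Prkca and Gm20425. Aldh1l1 followed at 6.62 ± 0.753 and Pck1 at 6.44 ± 0.509. Pancreas and stomach genes were marked in 7 of 27 cases (25.9%, exact p = 4.00e-05, adjusted p = 9.32e-05), with the duodenal and pancreatic regulator Pdx1 at 6.19 ± 4.15, Mafa at 5.85 ± 0.0504, Nkx6-1 at 4.63 ± 1.65 and Cela1 at 4.57 ± 0.499. Atp4a, Atp4b, Cel and Cela2a had none. Of 30 skeletal and cardiac muscle genes 9 were marked (30.0%, exact p = 0.000126, adjusted p = 0.000236), and Actn3 at 23.2 ± 1.49 and Mylpf at 22.9 ± 2.32 had only peaks shared with Zdhhc24 and Tbc1d10b. Myl3 had 13.9 ± 1.81, with a peak shared with Pth1r, and Hcn4 9.83 ± 0.751, while Acta1, Ckm, Myf5 and Myf6 had none. Brain and eye genes had a peak in 10 of 34 cases (29.4%, exact p = 2.86e-05, adjusted p = 7.28e-05), led by Satb2, a regulator also active in the colon, at 18.9 ± 2.51, Mbp at 18.6 ± 2.27, Slc17a7 at 6.83 ± 1.34 and En1 at 5.42 ± 1.63. Crx, Cryaa, Cryba1 and Emx2 had none. Without replicate 2 the brain and eye share was 55.9% and the call ended (adjusted exact p = 0.191). Against CpG-matched genes the liver and pancreas calls ended (adjusted permutation p = 0.932 and 0.328). Ranges of the adjusted exact or permutation p over the 10 alternatives were 1.20e-06 to 0.932 for liver, 1.68e-05 to 0.328 for pancreas and stomach, and 3.10e-07 to 0.191 for brain and eye genes.

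The genes least often marked were those of germ cells, skin and chemosensory receptors. Of 30 germ cell genes only Dazl had a peak, at 13.6 ± 0.969 (3.33%, exact p = 6.38e-13, adjusted p = 5.96e-12, Fisher's exact test), and Acr, Akap4, Bmp15 and Ddx4 were among the rest. In the list of epidermis and hair genes Krt10 at 13.8 ± 2.86 and Dsc3 at 4.95 ± 0.588 were marked, 2 of 25 genes (8%, exact p = 2.69e-09, adjusted p = 1.88e-08), and Casp14, Dsg1a, Dsg3 and Flg were not. Among 1134 olfactory receptor genes 2 had a peak (0.176%, with a p too small for the software to represent), Olfr94 at 6.09 ± 1.80 and, named after its values were seen, Olfr56, whose peak was shared with Ifi47. Of 329 vomeronasal receptor genes 1 had a peak (0.304%, exact p = 5.84e-153, adjusted p = 8.18e-152), Vmn1r4 at 16.4 ± 2.11, and this peak also lay in the window of Nt5c3. In all, 10 of the 28 lists were marked more often than other genes, counting 2 groups of Hox genes described below, and 12 less often.

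**Figure D2:**
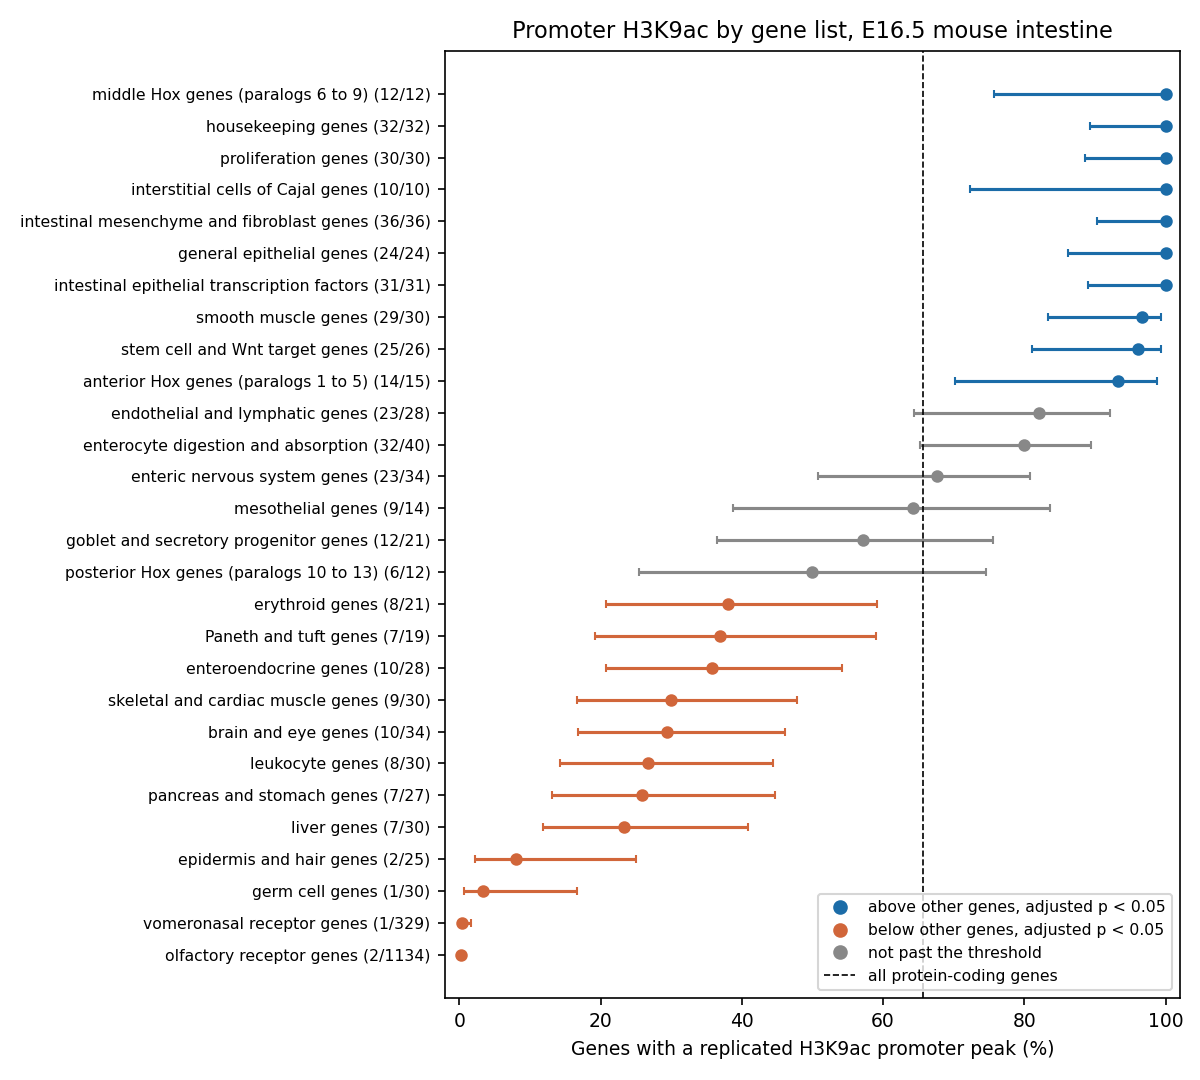
Percentage of each gene list with a replicated H3K9ac promoter peak (x axis), with 95% Wilson intervals and the number marked over the number of members beside each list, and the 65.7% of all protein-coding genes as a dashed line. Blue lists were above and orange lists below all other genes at an adjusted p under 0.05, and the shares ran from 0.176% of olfactory receptor genes to 100%.

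Among marked genes, those of single cell types mostly carried weaker promoter peaks than the average gene, and housekeeping genes stronger ones. The housekeeping median was 24.3 against a mean of 16.9 for random lists of the same size, the only list above (adjusted permutation p = 0.00048, permutation test, two-sided, 100000 random lists, over 24 lists). Of the others 16 lay below. Enterocyte genes had a median of 7.37, enteric nervous system genes 5.22 and endothelial genes 5.76 (adjusted permutation p = 0.00016 each, from the smallest p the permutations can give, 2e-05). Brain and eye genes had 4.49 (adjusted permutation p = 0.00024), mesothelial genes 5.12 and pancreas and stomach genes 4.52 (0.00144 each), enteroendocrine genes 6.24 (0.00312), leukocyte genes 5.48 (0.0032) and smooth muscle genes 10.1 (0.00538). Posterior Hox genes had 4.93 (0.0137), mesenchyme genes 11.7 (0.0154), liver genes 6.51 (0.0225), Paneth and tuft genes 6.96 (0.0313), skeletal and cardiac muscle genes 7.96 (0.033), middle Hox genes 9.76 (0.0477) and genes of interstitial cells of Cajal 9.33 (0.0496). The medians of epithelial transcription factors (14.7), general epithelial genes (12.9), stem cell and Wnt target genes (13.8), proliferation genes (18.1), anterior Hox genes (14.6), goblet genes (10.8) and erythroid genes (9.84) did not pass the test. Against random genes of matched promoter CpG content the enterocyte median was no lower, at 7.37 against 7.34 (adjusted permutation p = 0.975), and the calls for smooth muscle, mesenchyme, Cajal, leukocyte, liver and striated muscle genes ended (adjusted permutation p = 0.104 to 0.989), while stem cell and Wnt target genes passed as lower (0.0245, range over 7 alternatives 0.0245 to 0.630). Goblet genes passed as lower with promoter windows of 2.5 kb (adjusted permutation p = 0.049, range 0.049 to 0.294). The Cajal call also ended without either replicate (adjusted permutation p = 0.0638 without replicate 1 and 0.0564 without replicate 2) and the middle Hox call without replicate 1 (0.0541). Over 7 alternatives the adjusted permutation p ran from 0.00012 to 0.975 for enterocyte genes, 0.0463 to 0.199 for Cajal genes and 0.0148 to 0.0925 for middle Hox genes.

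Hox genes, which pattern the gut along its length, were marked more often than other genes in their anterior and middle groups, and the posterior group did not pass the test. Of the anterior genes (paralogs 1 to 5) 14 of 15 had a promoter peak (93.3%, exact p = 0.0268, adjusted p = 0.0341, Fisher's exact test), and of the middle genes (paralogs 6 to 9) all 12 (exact p = 0.0113, adjusted p = 0.0166). The posterior genes (paralogs 10 to 13) had one in 6 of 12 cases (50%, exact p = 0.361, adjusted p = 0.404). The highest anterior genes were Hoxb2 at 21.9 ± 6.59, Hoxb4 at 21.8 ± 2.55 (chromosome 11, 96318267 to 96321638), Hoxa4 at 20.8 ± 0.779 and Hoxc4 at 16.8 ± 0.463. The highest middle genes were Hoxb6 at 16.1 ± 0.283, Hoxb7 at 15.6 ± 3.05, Hoxb8 at 11.9 ± 0.821 and Hoxd8 at 11.8 ± 0.188. Posterior genes reached 5.61 ± 0.949 at Hoxa10, 5.31 ± 0.0748 at Hoxa11, 4.93 ± 0.106 at Hoxa13, 4.64 ± 1.67 at Hoxd10 and 4.22 ± 0.905 at Hoxd11. In cluster d the anterior gene Hoxd1, at 3.44 ± 0.693, lay below the posterior Hoxd10 and Hoxd11. Hoxb13 had a peak in the replicated list and none in its window in either per-replicate list. Genes without a replicated peak were Hoxb1, Hoxc10, Hoxc11, Hoxc12, Hoxc13, Hoxd12 and Hoxd13, and every other Hox gene had one. Spread between the replicates was widest at Hoxb3, with 22.3 in replicate 1 and 7.5 in replicate 2. These values are from different peaks, since the replicate 2 peak of 16.5 that overlapped the replicate 1 peak lay outside the promoter window. The anterior call ended without replicate 2 (adjusted exact p = 0.0712), and both higher calls ended against CpG-matched genes (adjusted permutation p = 0.544 for anterior and 0.789 for middle genes). Posterior genes were then below their matched genes, of which 95.3% were marked (adjusted permutation p = 0.000622). The adjusted exact or permutation p ran over the 10 alternatives from 0.00418 to 0.544 for anterior, 0.00185 to 0.789 for middle and 0.000622 to 0.806 for posterior genes.

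**Figure D3:**
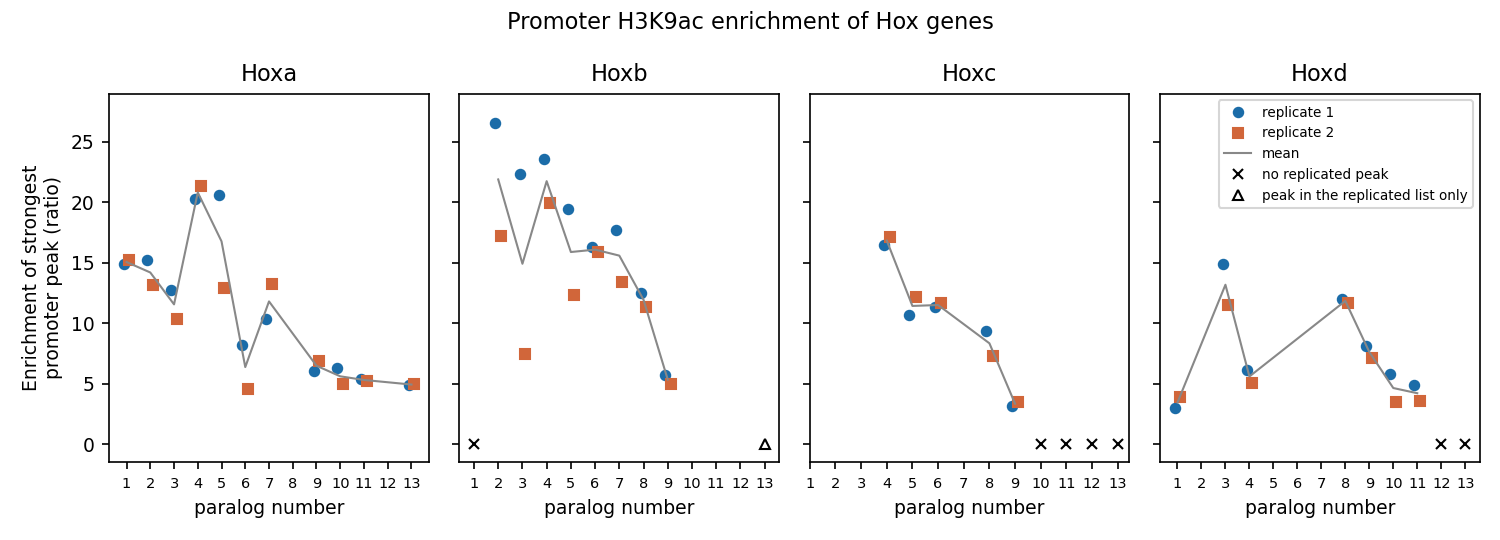
Enrichment ratio of the strongest promoter peak (y axis) of each Hox gene by paralog number (x axis) in the 4 clusters, with replicate 1 as circles, replicate 2 as squares and their mean as a line. Crosses at 0 are the 7 genes with no replicated peak, and the open triangle is Hoxb13, which had a replicated peak and none in either per-replicate list. Values ran from 26.6 at Hoxb2 to 2.95 at Hoxd1, both in replicate 1.

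Away from promoters, epithelial transcription factors and stem cell and Wnt target genes had the most marked sites per gene among the lists that passed. This order is of the mean counts, not of their ratios to matched random genes. Of the replicated peaks 19158 (44.8%) lay more than 2.5 kb from every protein-coding start, at a median distance of 16.5 kb from the nearest. Epithelial transcription factors had 5.87 distal peaks per gene against 1.19 for random genes with territories of matched length, 4.92 times as many (adjusted permutation p = 0.0028, permutation test, one-sided, 10000 random lists, over 28 lists, from the smallest p they can give, 0.0001). Stem cell and Wnt target genes had 5.54 against 1.43 (adjusted permutation p = 0.0126), general epithelial genes 2.38 against 0.721 (0.0149), anterior Hox genes 1.80 against 0.414 (0.0336), mesenchyme genes 3.78 against 1.48 (0.0358), and smooth muscle genes 2.93 against 1.16 and middle Hox genes 1.00 against 0.242 (0.038 each). The other 21 lists did not pass, among them housekeeping genes at 1.41 against 0.627 (0.0682), leukocyte genes at 1.63 against 0.749 (0.0883) and goblet genes at 2.00 against 1.02 (0.167). Among list genes most distal peaks were assigned to Irf8 (31, chromosome 8, 120736358 to 120756694), Hes1 (30), Ephb2 (26), Foxf1 (26), Mylk (19), Sox9 (18), Ppara (15), Tbx3 (15), Ywhaz (15) and Gata4 (14, as many as Hnf4a, Lrig1, Prdm1 and Tcf7l2). A distal peak was given to the gene of the nearest start, which need not be the gene it acts on. The 31 peaks given to Irf8 made up much of the mean of 1.63 over 30 leukocyte genes. Irf8 lies on chromosome 8 between Gse1, with 107 distal peaks, and Foxf1. Among anterior Hox genes, Hoxc4 had 10 distal peaks and Hoxb3 had 6, more than any other. Distal peaks were counted before merging, so some may lie in the promoter domains described below. Beyond 10 kb only the stem cell and Wnt list passed, at 4.46 against 1.09 (adjusted permutation p = 0.0364), and without replicate 1 the smooth muscle and middle Hox calls ended (0.0597 and 0.0644). Adjusted permutation p-values over 7 alternatives ran from 0.022 to 0.0739 for smooth muscle, 0.0215 to 0.306 for middle Hox and 0.0056 to 0.0364 for stem cell and Wnt target genes.

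**Figure D4:**
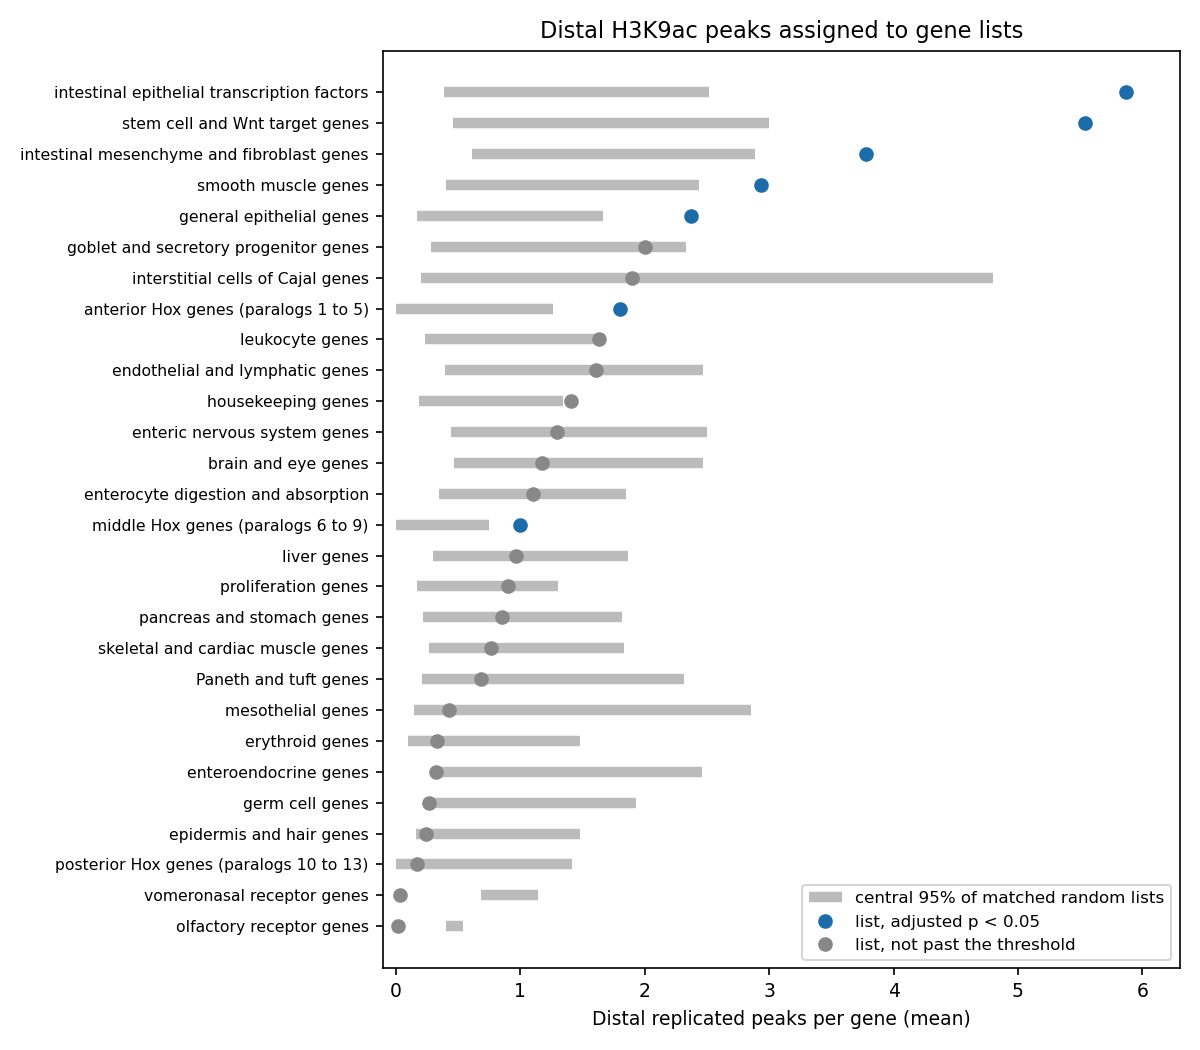
Mean number of distal replicated peaks per gene (x axis) in each gene list, over the central 95% of 10000 random lists matched on the length of the gene's territory (grey bars). Blue points are the 7 lists with an adjusted p under 0.05, of which the epithelial transcription factors had the highest value, 5.87.

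Broad domains of H3K9ac were more frequent in 8 of the 24 lists tested, anterior Hox genes and epithelial transcription factors among them. After replicated peaks at most 1 kb apart were merged, the widest 5% of promoter domains were 4867 bp or more, against a median of 1790 bp. The widest covered 32483 bp of the Hoxb cluster (chromosome 11, 96298090 to 96330572) and held a start each of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. The 5′ end of Hoxb6, at 96292476, lay outside it, and Hoxb3 had another start at the next domain, of 15061 bp. A domain of 24530 bp covered Hoxa1, Hoxa2 and 5730596B20Rik (chromosome 6, 52157520 to 52182049), one of 22280 bp Foxf1 (chromosome 8, 121070514 to 121092793), one of 20134 bp Bahcc1 and one of 17125 bp Meis2, a Hox cofactor gene. Wide domains were found at 9 of 14 marked anterior Hox genes (adjusted exact p = 1.51e-07, Fisher's exact test, over 24 lists), 15 of 31 epithelial transcription factors (9.38e-10), 12 of 36 mesenchyme genes (4.34e-06), 8 of 24 general epithelial genes (0.000266), 8 of 32 housekeeping genes (0.002), 7 of 29 smooth muscle genes (0.00478), 4 of 12 middle Hox genes (0.0139) and 5 of 25 stem cell and Wnt target genes (0.0417). Other marked genes had one in 5.80 to 5.87% of cases. Neighbouring Hox genes shared domains, so the tests of the Hox lists counted the same domain more than once. Hoxb3, Hoxb4, Hoxb5 and the middle gene Hoxb6 were all given the domain of 32483 bp. Hoxa1 and Hoxa2 shared that of 24530 bp, and Hoxb7 and Hoxb8 one of 5568 bp. The other 16 lists did not pass. Without merging, the calls for anterior Hox, middle Hox and housekeeping genes ended (adjusted exact p = 0.0738, 1 and 0.283). The stem cell call ended without replicate 1 (0.206) and the housekeeping call without replicate 2 (0.124). Merging gaps up to 3 kb ended the calls for smooth muscle, stem cell and housekeeping genes (adjusted exact p = 0.822, 0.275 and 0.232), an enrichment of at least 4 that for middle Hox genes (0.059), and the combined list that for stem cell genes (0.189). Goblet genes, at 3 of 12 and an adjusted exact p of 0.0801 here, passed in 4 of 8 alternatives, with the combined list (0.00836), an enrichment of at least 4 (0.00662), the widest 10% (0.00379) and without replicate 2 (0.00266), and ranged up to 0.868. Posterior Hox genes passed with gaps up to 3 kb merged (adjusted exact p = 0.0228, range up to 1). Over 8 alternatives the adjusted exact p ran from 7.53e-10 to 0.0738 for anterior Hox, 9.75e-06 to 1 for middle Hox, 0.00012 to 0.283 for housekeeping, 4.51e-06 to 0.822 for smooth muscle and 0.001 to 0.275 for stem cell and Wnt target genes.

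**Figure D5:**
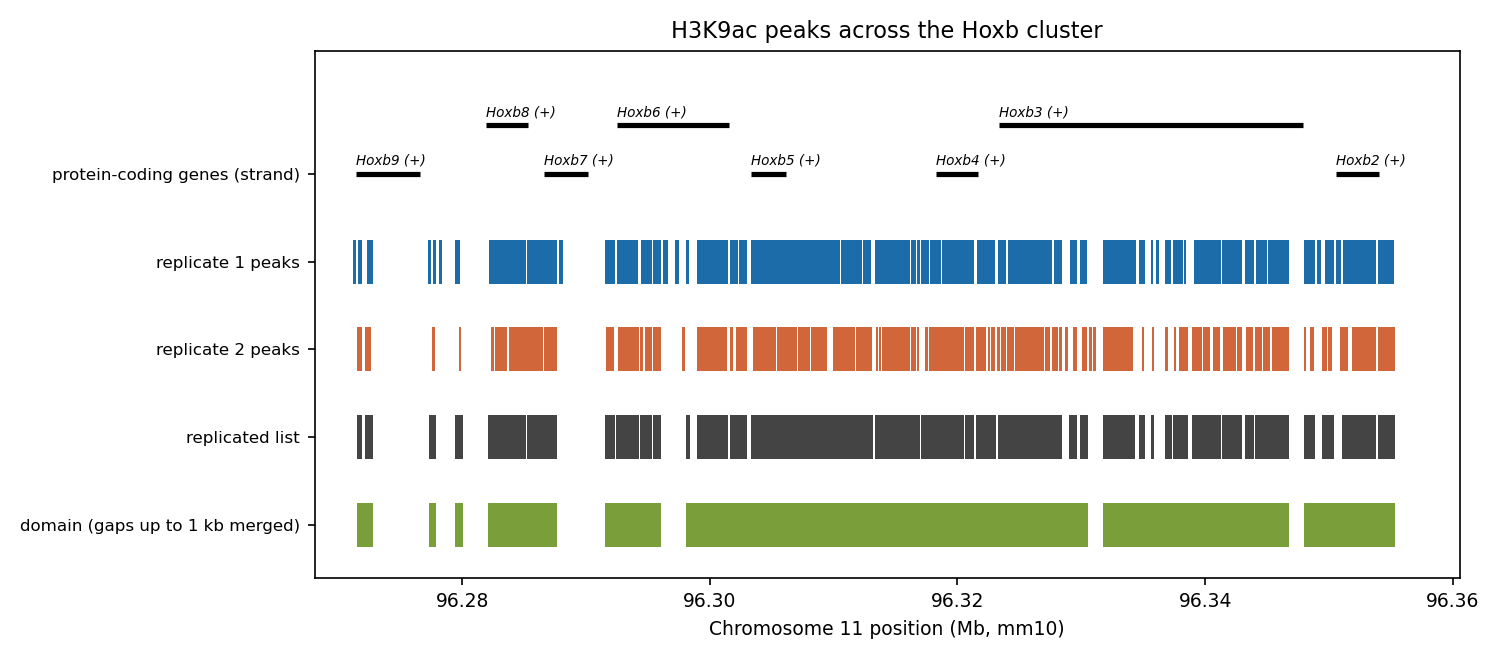
Map of 92.5 kb of mouse chromosome 11 (x axis, position in Mb, mm10) with the protein-coding Hoxb genes and their strand, the peaks of each replicate, the replicated peaks, and the domains made by merging gaps of up to 1 kb. The widest domain, 32483 bp from 96298090 to 96330572, holds a start each of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. The 5′ end of Hoxb6 and another start of Hoxb3 lie outside it.

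The KLF, E-box, CTCF, FOX and HNF4 sequence strings were more frequent around the summits of distal peaks than in windows 5 kb downstream. Only KLF and the E-box passed as more frequent in all 5 alternatives as well. In the 500 bp around the summit, 2.17% of 19156 distal peaks held the CTCF string CCASYAGRKGGC against 0.472% of 14620 windows 5 kb downstream without a peak, a ratio of 4.60 (adjusted exact p = 8.25e-43, Fisher's exact test, two-sided, over 20 strings). The KLF string CCCCACCC was in 17.7% against 9.17% (ratio 1.93, adjusted exact p = 1.71e-113), the E-box CAGCTG in 37.8% against 22.7% (1.66, 4.14e-195), the FOX string TGTTTAC in 6.93% against 5.85% (1.18, 0.000279) and the HNF4 string CAAAGTCCA in 0.981% against 0.725% (1.35, 0.0235). Ratios of 4.83 for NFI, 2.43 for NRF1, 2.33 for ETS and 1.11 for TEAD also passed. NFI passed in none of the 5 alternatives, where its ratio lay between 1.27 and 2.85. Among shuffled strings of the same base composition that occurred in the windows, the ratio was reached by 0 of 20 for FOX and TEAD, 0 of 18 for NFI, and 0 of the 7 that the bases of the KLF string allow. It was reached by 2 of 18 for CTCF, 2 of 19 for ETS, 4 of 20 for HNF4 and for the E-box, and 9 of 15 for NRF1. Lower ratios passed for CDX (0.687), NR5 (0.713) and HAND (0.967), and 8 strings, among them GATA (0.957), did not pass. Distal peaks were richer in GC than the windows, 53.4% against 46.6%, and with windows of matched GC content the order changed. CDX then had a ratio of 1.13 (adjusted exact p = 0.00413), GATA 1.25 (0.000597), FOX 1.71 (8.99e-20), HNF4 1.74 (0.00346) and MEF2 1.75 (0.00283), while KLF fell to 1.12 (0.00706), the E-box fell to 1.23 (4.27e-19) and NRF1 (1.10), ETS (2.18), NFI (2.5) and NR5 (0.801) no longer passed among the 8940 peaks that were left. Of 20 shuffled strings each, 8 reached this ratio for CDX, 4 for HNF4, 2 for GATA and 0 for FOX and MEF2. In the central 200 bp only KLF and the E-box passed as more frequent, and the ratios of CTCF and FOX were 0.813 and 0.979. TEAD (1.11), NFI (2.85), ETS (1.45), HNF4 (1.06) and NRF1 (1.08) kept ratios above 1 there without passing, and GATA passed as less frequent (0.783, adjusted exact p = 0.0022). Over 5 alternatives the adjusted exact p of CDX, GATA, FOX, HNF4 and MEF2 ran from 1.06e-73, 0.000597, 8.99e-20, 2.83e-05 and 0.00283 to 0.00413, 0.835, 0.84, 0.876 and 0.681 in that order. These ranges take both directions together. CDX passed as more frequent only with matched GC content. It passed as less frequent in 200 bp (ratio 0.469), with windows upstream (0.707), without replicate 1 (0.740) and without replicate 2 (0.706, the lowest p).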

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

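The tests of cells from other organs, of one replicate alone and of where strings lie around summits were chosen after the results they measure were seen.

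Peak calls were also present in parts of the data that the comparisons leave out. On unplaced or unlocalised scaffolds the replicated list held 6 peaks, above the 3 that a count of 0 allows, which is no test of these calls, and they were left out above because the comparisons used assembled chromosomes. Their enrichments were 21.96 on a scaffold of chromosome 4, 4.18 on an unplaced scaffold, and 15.7, 8.29, 6.94 and 3.34 on scaffolds of the X chromosome. Starts of long non-coding RNA (lncRNA) genes more than 2.5 kb from every protein-coding start held a replicated peak in 935 of 7950 cases (11.8%), against 1.74% on average and 2.08% at most for randomly placed windows of the same size. High entries, named after their values were seen, were 1810026B05Rik at an enrichment of 56.3, Mir17hg, the host of a microRNA cluster, at 35.2, Snhg6 at 34.5, Epb41l4aos at 32.3 and Dancr at 32.1, each from the combined list. These were not tested further.

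Among 121 marker genes of liver, pancreas and stomach, striated muscle, and brain and eye, none of them in another list, 33 had a promoter peak, which cells of those organs in the pools might explain. In none of the 4 lists did the marked share lie above CpG-matched random genes, with 23.3% for liver (central 95% of random lists 13.3 to 40%), 25.9% for pancreas and stomach (22.2 to 48.1%), 30.0% for muscle (36.7 to 66.7%) and 29.4% for brain and eye (73.5 to 88.2%). A few cells of any of these organs cannot be told apart from their absence, because a share of genes does not show which cells a peak came from, and Afp, Ahsg and Alb had no peak while Ttr, named after its values were seen, had one of 4.48. A window shared with a neighbouring gene was the only source of peaks for 12.1% of the 33 genes against 16.1% of other marked genes (Fisher's exact p = 0.811), too few to decide. The genes with a peak had a median of 39 CpG per promoter against 19 without (permutation p = 0.00526). CpG-rich promoters may account for part of the pattern, but not for the shares of muscle and of brain and eye genes. Those shares lay below the ranges of CpG-matched random genes. Enrichment rose with CpG count over all genes with values in both replicates, so such a link is not particular to these lists. No biological explanation was tested.

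Promoter enrichment fell with paralog number across the 31 Hox genes with a replicated promoter peak and a value in both replicates. The rank correlation within clusters was −0.69 (permutation p = 0.0003), and genes of 1 tissue are not independent replicates. By cluster it was −0.80 in a, −0.74 in b, −0.90 in c and −0.14 in d. Hoxb1, of paralog 1, was left out for want of a replicated peak, and it runs against the trend in cluster b. The other genes left out, Hoxb13, Hoxc10, Hoxc11, Hoxc12, Hoxc13, Hoxd12 and Hoxd13, were posterior. The trend was not among the comparisons planned before the data were examined. Neighbouring genes in the same domain, such as Hoxb4 and Hoxb5, were permuted as separate genes. Adjusted for promoter CpG count the correlation was −0.75, outside the central 95% of permutations (−0.42 to 0.41, permutation p = 4e-05). CpG count itself rose with paralog number, with a rank correlation within clusters of 0.48 (permutation p = 0.0196). Over all 14148 genes with a value in both replicates, enrichment rose with CpG count (Spearman's rho 0.506), so CpG content ran against the fall. The weaker of the replicates taken alone had −0.62 (permutation p = 0.002). These values argue against CpG content and against 1 replicate as the whole cause. What stays open is reads placed in error between paralogs, which cannot be examined without reads, and a mixture of gut regions with different Hox codes. No biological explanation was tested, since the design has 1 tissue and 1 stage.

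Of the 9 strings more frequent in 500 bp windows around distal summits, CTCF among them, only KLF and the E-box also passed in 200 bp windows. Of the 7 others, 2, CTCF and NRF1, were denser 100 to 240 bp from the summit, relative to within 100 bp, than each of their shuffled strings with a ratio (19 and 20, since 1 shuffled CTCF string had no occurrence near the summit and 1 beside it), whereas the ratios of HNF4 (1.70), ETS (2.00), FOX (1.19), TEAD (1.026) and NFI (0.977) lay inside the range of theirs. Whether the strings lie beside the summit is left open, because a lower density near it is nearly what the loss in shorter windows already shows, and TEAD lost its call with a ratio of 1.11 in both windows. For CTCF the ratio of densities was 7.80 (exact 95% interval 5.48 to 11.4) against 0.929 pooled over its shuffled strings. Single shuffled strings, most with few occurrences, ranged from 0 to 7.11. CTCF was also chosen for the loss that this ratio restates, so base composition as its cause is not excluded. No biological explanation was tested.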

How the results depend on the processing

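The results for replicated peaks in both per-replicate lists and for peaks in the window of no other gene were chosen after the data were seen.

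Over their alternatives, the share of peaks overlapping between replicates stayed between 38.5 and 80.5%, genes with a promoter peak between 12057 and 15136, and the share of peaks at promoters between 27.1% in the combined list and 61.3% of replicated peaks at an enrichment of at least 4. Requiring an enrichment of at least 4 left 32423, 31436 and 29749 peaks in the replicate 1, replicate 2 and combined lists, as fewer peaks qualify, and moved the Spearman's rho between replicates from 0.841 to 0.883. It was 0.855 with a −log10 q of at least 2, 0.812 with an overlap of 1 bp and 0.912 with 50% of both peaks. The cause was not tested.

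For single lists and strings, 242 of 280 alternatives kept the direction and side of the threshold for promoter marking, 146 of 165 for enrichment, 186 of 196 for distal peaks, 177 of 192 for broad domains and 70 of 99 for strings. All 22 calls of promoter marking held among replicated peaks with partners in both lists, and 19 held among peaks in the window of no other gene, where Paneth and tuft, enteroendocrine and erythroid genes no longer passed. Calls of promoter marking ended for Paneth and tuft, enteroendocrine, Cajal, leukocyte, and brain and eye genes with the combined list, for Cajal and anterior Hox genes with the 5′ end alone, for anterior and middle Hox genes at an enrichment of at least 4, and for Paneth and tuft genes with windows of 2.5 kb. Calls of enrichment ended for Paneth and tuft, Cajal, liver and striated muscle genes with the 5′ end alone, for Cajal genes with the combined list, and for Cajal and middle Hox genes with windows of 2.5 kb. Calls of distal peaks ended for anterior Hox genes with the combined list and for middle Hox genes among peaks with partners in both lists. Here the cause was not tested. With CpG-matched random lists 5 lists, not 10, were marked more often, the erythroid share of 38.1% lay above the matched 30.0%, 10 lists, not 16, had a lower enrichment, and the enterocyte median of 7.37 lay just above the matched 7.34. Matching removes the share of each difference that goes with promoter CpG content. With the 5′ end of the gene alone also 10 lists had a lower enrichment, of 22 with enough genes. Beyond 10 kb 1 list, not 7, had more distal peaks, and without merging 5, not 8, had more broad domains. For these counts the cause was not tested.

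In 200 bp windows 2 strings, not 9, passed as more frequent, and the ratios of FOX (0.979), CTCF (0.813) and HAND (1.02) changed side. With GC-matched windows 1 string, not 3, passed as less frequent, CDX (1.13) and GATA (1.25) changed side, and HNF1 had no ratio because no matched window held it. Without replicate 1, AP1 and MEF2 passed as more and SOX as less frequent, without replicate 2, AP1, HNF1 and ERYTHROID as more and SOX as less frequent, and NFI did not pass in either case. Windows upstream added MEF2 and removed NFI. The lower call of HAND ended without replicate 1 (ratio 0.9997, adjusted exact p = 0.986) and without replicate 2 (1.02, adjusted exact p = 0.0891). It held with windows upstream (0.954, adjusted exact p = 0.00314) and with GC-matched windows (0.905, adjusted exact p = 3.98e-06). For these the cause was not tested. Weak peaks overlapped least, and with no counts among the files used the part that depth has in this could not be measured.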

Other observations

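All values of this part were chosen after the data were seen.

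Marked genes on the X chromosome had weaker promoter peaks than marked autosomal genes. A replicated promoter peak was present at 442 of 948 X-linked protein-coding genes (46.6%) against 67.2% of autosomal genes, and leaving out olfactory and vomeronasal receptor genes gave 47.1% against 72.2%, a difference in shares that was not tested. The median enrichment of 430 X-linked genes was 10.03, against a mean of 14.9 for random autosomal lists matched on promoter CpG content (ratio 0.672, permutation p = 0.0002, the smallest 10000 permutations can give). In the replicates taken alone the ratio was 0.672 and 0.665. The pools held both sexes in unknown proportions.

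Outside the gene lists, most distal peaks were assigned to Gse1 (107), Zmiz1 (62), Zfp36l1 (48), Zfp36l2 (45) and Sept9 (42), none of them corrected for the length of the gene's territory. Among merged domains, 1 of 18100 bp held no protein-coding start (chromosome 18, 61648794 to 61666893). Others covered starts of Cxxc5 (16257 bp), Ptch1 (16018 bp), Tbx2 (15972 bp) and Zmynd8 (15328 bp).

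Replicate 1 had higher promoter enrichments than replicate 2, with a median log2 difference of 0.16 over 14148 genes. For each of the 24 lists with enough genes, the median difference lay inside the central 95% of random lists of the same size.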
